A study of Mus musculus with 21 samples.

How the data were processed

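RNA-seq of T cells sorted from mouse spleen was measured in 21 libraries of 4 groups: wild type (WT, n = 5), mice lacking Tet2 in all cells and Tet3 in T cells (DKO, n = 5), and DKO cells after a first (TX1, n = 4) or second (TX2, n = 7) transfer into recipients. Per the labels, all WT libraries are male, and DKO, TX1 and TX2 include 1, 1 and 3 female libraries. The deposited gene files hold counts, that is, whole-number reads per Ensembl gene in the layout of STAR, for 55487 genes. The authors' notes name fastp 0.21.0, STAR 2.7.5a, DESeq2 and the builds mm10 and GRCm38. The deposited clonotype tables hold counts of reads per receptor sequence for 1 chain; the tool behind them is not given in the sources used here, and their column layout is that of MiXCR's export.

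The larger strand column held a median share of 0.507 of stranded counts, so the unstranded column was used. Reads assigned to genes ranged from 26918548 to 30730877 per library, and 16.8 to 23.4% of reads lay in the summary lines for unmapped, multimapping, ambiguous and unannotated reads. Symbols and coordinates came from GENCODE M21 on GRCm38, which matched 55141 of the 55487 identifiers. Reads that map to several places are set aside in these files, so levels of genes with near-identical copies are uncertain. Intervals and floors given with single-library shares and with genes without reads cover counting error only.

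Each pair of groups was fitted alone in edgeR 4.0.16 (R 4.3.3) with TMM normalisation, filterByExpr and the robust quasi-likelihood test. Genes with a Benjamini-Hochberg adjusted p below 0.05 are said to rise or fall, all tests are two-sided, and errors of log2 fold changes are standard errors. Group means are in CPM with the TMM factors of the pair, while values per library use factors over all 21 libraries and so differ slightly. On simulated data with 200 changed genes per comparison, the test recovered 62% (DKO against WT), 29% (TX1 against DKO), 59% (TX2 against DKO) and 32% (TX2 against TX1) of changes of 2-fold, and 99, 72, 78 and 73% of changes of 4-fold, with 6, 6, 2 and 3 false calls. These shares come from a single random draw and moved between draws. Each library was simulated as independent, whereas several TX2 libraries carry the same clone. The shares and false calls of the 2 TX2 comparisons therefore do not cover that dependence.

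Named genes followed a rule set before the data were examined. It takes the 6 largest rises and 6 largest falls with a mean of at least 5 CPM and no overlap between groups. Receptor and immunoglobulin segments, Y-linked genes, Xist, Tsix and unnamed genes are left out, while other X-linked genes are kept. It adds up to 3 called members of each gene list, and 12 genes in every comparison. The rule gives 294 pairs of gene and comparison; of these, 174 were printed, and the list members left out were left out after their values were seen. Some genes that the rule names are withheld and not reported here. The 31 gene lists, 12 of them markers of other cells, were tested in limma 3.58.1 with camera at a correlation of 0.01, with an estimated correlation and fry as alternatives. Lists are described where camera called them, and others where a gene named as changed belongs to them.

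The share of the most abundant clonotype and the log10 number of clonotypes, drawn to 2633 TRA or 3763 TRB reads, were compared by exact permutation tests, adjusted over 16 tests. TRB tables were analysed for 18 libraries (WT replicates 1, 3 and 4, DKO replicates 1 to 4, and all transferred libraries). For expression along chromosomes, log2 CPM of 8375 autosomal genes with a WT mean of at least 3 was set against the WT mean (each WT library against the mean of the others), and the SD of the medians of 19 autosomes was compared by exact permutation, adjusted over 3 tests. On simulated data a 1.5-fold gain of a chromosome gave a median shift of 0.59.

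Alternatives set before the data were examined were DESeq2 1.42.0, other size factors, no filter on low counts, a fold change threshold, the strand column, 1 fit of all groups, sex or replicate number as covariates, male libraries alone, DKO labelled young left out, and each library left out. Replicate numbers were taken as not pairing the samples (see sensitivity.md). Within groups, multimapping, and between libraries, low counts of clonotypes dominant elsewhere, parted the libraries into 2 sequencing rounds: WT, DKO and TX1 replicates 1 to 3, and all others. These low counts were taken as carried-over reads, which was not tested. The highest were 0.11% of TRA and 0.29% of TRB reads in TX1 replicate 4, of the receptor of TX2 replicates 1 to 4. There a minor clone cannot be told apart from carried-over reads. The rounds, and the TX2 libraries 1 to 4 and 5 to 7, were defined from the data, and alternatives built on them were added later. DKO replicates 4 and 5, the DKO libraries of the later round, are also the ones labelled young. In DKO the round and that label cannot be told apart. Of other splits of the samples, 40 were drawn per comparison, including the real one, to keep within the time limit, and for TX2 against DKO the 21 splits with recipients of one clone summed were added.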

Results

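RNA from T cells sorted from mouse spleen was sequenced in 21 libraries, and gene counts were compared between 4 groups. Wild type mice (WT) gave 5 libraries, and mice lacking Tet2 in all cells and Tet3 in T cells (DKO) gave 5, of which 2 (replicates 4 and 5) carry the label young. TET enzymes oxidise 5-methylcytosine and so take part in DNA demethylation. DKO CD4 T cells that had been transferred into recipient mice gave 4 libraries after a first transfer (TX1) and 7 after a second (TX2). WT and DKO cells were sorted on CD4, TCRb and absence of CD25 and of the CD1d tetramer, whereas transferred cells were sorted on the donor form of CD45, so the gate and the transfer changed together. Reads assigned to genes ranged from 26918548 to 30730877 per library. Tables of T cell receptor clonotypes were used for the alpha chain (TRA) in 21 libraries and for the beta chain (TRB) in 18. The chi-square per gene between libraries of a group was 6.94 or higher, where sampling noise alone gives about 1, so none was treated as a duplicate.

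The comparison of DKO with WT asks what CD4 T cells express once both enzymes are lost. Tet3 (chromosome 6, 83362373 to 83459084, GRCm38) fell from 196 ± 17.2 CPM (SD, n = 5) in WT to 94.5 ± 7.03 (n = 5) in DKO, a log2 fold change of -1.05 ± 0.09 (SE; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 1.90e-05). Tet2 (chromosome 3, 133463679 to 133545139) was at 47.3 ± 6.14 CPM in DKO and 43.4 ± 8.5 in WT (adjusted p = 0.501). Counts over the whole gene include reads outside a deleted part, so the Tet2 level does not check the genotype. Tet1, the remaining member of the family, fell from 35.1 ± 8.14 to 8.37 ± 3.12 CPM (log2 fold change -2.07 ± 0.28, adjusted p = 0.000268).

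Naive and quiescence genes fell in DKO, and genes of cell division, inhibitory receptors and T follicular helper cells rose. Of 16 naive and quiescence genes measured, 14 fell and 0 rose. Among them, Dapl1 fell from 103 ± 7.91 to 8.66 ± 4.74 CPM (SD, n = 5 per group) and Igfbp4 from 1048 ± 236 to 184 ± 126 CPM. All 26 mitosis genes rose, with Ccnb2, a mitotic cyclin, at 84.4 ± 28.3 CPM against 9.82 ± 4.06, and Aurkb, a mitotic kinase, at 49.5 ± 29.2 against 5.89 ± 3.02. Of 28 DNA replication genes, 26 rose, including Mcm10 (log2 fold change 3.10 ± 0.35) and Rrm2 (2.73 ± 0.35). Mki67, a proliferation marker, reached 359 ± 146 CPM against 52.0 ± 11. Of 14 inhibitory receptor genes, 11 rose, among them Lag3 (log2 fold change 4.60 ± 0.53), Cd160 (4.14 ± 0.32) and Pdcd1, the gene of PD-1 (2.66 ± 0.48). Of 13 T follicular helper genes, 11 rose, including Icos (604 ± 283 against 116 ± 30.2 CPM), Tox2 (log2 fold change 3.26 ± 0.43) and the cytokine Il21 (2.90 ± 0.94, adjusted p = 0.0284). The call of Il21 rested on DKO replicate 2: without it the log2 fold change was 1.19 ± 0.55 (adjusted p = 0.105).

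Of 18 activation genes 13 rose and 1 fell, with Anxa2 at 421 ± 311 against 34.4 ± 13.5 CPM and S100a6 at 252 ± 181 against 22.5 ± 8.66. Of 22 cytotoxic and NK receptor genes 11 rose, among them Gzma (log2 fold change 4.55 ± 0.75) and Xcl1 (4.67 ± 0.48), and of 15 glycolysis genes 11 rose, with Hk2 at 2.74 ± 0.38 and Tpi1 at 2.32 ± 0.28. Adjusted over the list alone, the counts that rose were 26 for mitosis, 27 for DNA replication, 12 for inhibitory receptors, 12 for T follicular helper cells, 14 for activation, 12 for cytotoxic and 11 for glycolysis genes, and 15 naive genes fell. By camera with a preset correlation, the adjusted p was 2.55e-09 for naive, 1.92e-15 for mitosis, 1.08e-15 for replication, 1.67e-05 for inhibitory receptor, 2.51e-06 for follicular helper, 9.40e-05 for activation, 0.000491 for cytotoxic and 8.04e-06 for glycolysis genes. No list kept its call with an estimated correlation (adjusted p = 0.394 for the first 6, 0.439 for the cytotoxic and 0.396 for the glycolysis genes). Dendritic cell markers were also called by camera (4 of 6 measured rose, 5 adjusted over the list alone, adjusted p = 0.0416, and 0.396 with an estimated correlation).

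Among regulators of helper lineages, Ahr rose by a log2 fold change of 2.16 ± 0.29 and Tbx21, the gene of T-bet, by 1.25 ± 0.41 (adjusted p = 0.0298). The list was not called (4 of 12 rose and 1 fell, camera adjusted p = 0.0808). The cytokine receptors Il23r (log2 fold change 6.00 ± 0.55) and Il2rb (1.89 ± 0.23) rose. Of 26 cytokine receptor and JAK-STAT genes 8 rose and 8 fell (10 and 9 adjusted over the list alone; camera adjusted p = 0.947). The chemokine receptors Ccr6 (3.66 ± 0.52) and Ccr4 (2.77 ± 0.46) rose. Of 19 chemokine receptor and homing genes 10 rose and 3 fell (11 and 4 adjusted over the list alone; 0.137). Of 18 T cell receptor signalling genes 5 fell and 3 rose, the same adjusted over the list alone, and the list was not called (camera adjusted p = 0.0715, and 0.394 with an estimated correlation); Cd6 (-2.02 ± 0.40) and Cd5 (-1.22 ± 0.14) were among those that fell. Uhrf1, which maintains DNA methylation, rose (2.57 ± 0.29) in a list of 15 methylation genes of which 2 rose and 3 fell (camera adjusted p = 0.452). Pmaip1 rose (3.33 ± 0.41) in a list of 19 p53 targets of which 7 rose and 3 fell (0.403). The counts of the helper lineage, methylation and p53 lists were the same adjusted over the list alone. With an estimated correlation these and the 2 receptor lists had an adjusted p of 0.394 or above. Single markers of other cells went both ways: Zbtb16, the gene of PLZF in innate-like T cells, rose from 0.680 ± 0.244 to 8.66 ± 4.41 CPM (n = 5 per group), Klrb1c rose by 3.40 ± 0.31, Pax5 by 4.59 ± 0.96 and Itgam by 2.79 ± 0.43, and Cd8b1 fell from 33.8 ± 3.61 to 2.77 ± 1.55 CPM. Without DKO replicate 2 the log2 fold change of Pax5 was 3.12 ± 0.57, still called. As lists, the markers of B cells (3 of 11 rose, camera adjusted p = 0.247), macrophages (2 of 13 rose and 1 fell, 0.475) and invariant NKT cells (2 of 5 rose and 1 fell, 0.247) were not called. Their counts were the same adjusted over the list alone, and the adjusted p was 0.439 or above with an estimated correlation. NK cell (2 of 4 rose) and CD8 T cell markers (1 of 2 fell) were too few for camera. Cd55, a regulator of complement, fell by 2.86 on the log2 scale (SE 0.40).

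Among the largest rises without overlap between the groups, Sntg2 had no read in WT and 16.5 ± 17.3 CPM in DKO, at least 152-fold higher with a floor of 3 reads per library. It was at 45.88 CPM in DKO replicate 2 and at 4.18 to 18.8 in the other DKO libraries, and was still called without that replicate. Scg2 (log2 fold change 9.05 ± 0.75), Mmp10 (7.85 ± 1.49), Pcsk1 (7.70 ± 0.64, 422 ± 326 against 2.03 ± 1.01 CPM), Epha3 (7.50 ± 1.45) and Cadm1 (7.03 ± 1.35) followed. DKO replicate 2 carried much of the size of 3 of these: without it Mmp10 was at 5.53 ± 0.73, Epha3 at 5.05 ± 0.69 and Cadm1 at 5.26 ± 0.85, each still called, and Scg2 was at 8.85 ± 0.73 and Pcsk1 at 7.15 ± 0.44. The largest falls were in Igsf23 (-5.85 ± 0.22), Gabrr2 (-5.66 ± 0.44), Tbc1d30 (-5.36 ± 0.38), Adh1 (-5.29 ± 0.31), Myo10 (-4.05 ± 0.30) and Tbc1d16 (-3.77 ± 0.48). Runx3 rose (0.47 ± 0.09, adjusted p = 0.00148) and Zbtb7b, the gene of ThPOK, fell (-0.76 ± 0.17, adjusted p = 0.00381). Cd4 was at 1419 ± 266 against 1486 ± 44.1 CPM (adjusted p = 0.690), and Ptprc (adjusted p = 0.698), Myc (0.139), Trp53 (0.102), Foxp3 (0.104) and Cd8a (0.117) did not pass the test.

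Over all 13700 genes tested, 5951 differed at an adjusted p below 0.05, 3110 higher and 2841 lower in DKO, and 34.1% of tested genes did not overlap between the groups, where chance gives 0.794%. Receptor segment genes made up 150 of those tested, of which 9 rose and 19 fell. Within the libraries numbered up to 3 the count was 3829, and within those numbered 4 and over it was 3217; an absolute log2 fold change above 1 left 2541 genes. DKO replicate 2 was the highest or lowest library for many of these genes (Lag3 1038 CPM against 319 in the next library, Il21 301 against 48.3), and the count without it was 5837. It is the only DKO library labelled female, so that fit is also the one of male libraries alone.

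TRA diversity was lower in DKO. The most abundant TRA clonotype took 21.7 ± 31.6% of TRA reads (SD, n = 5) in DKO and 0.880 ± 0.671% (n = 5) in WT, higher in 5 of 5 DKO libraries than in any WT library (two-sided exact permutation test, p = 0.00794, the smallest the design allows, adjusted p = 0.0181 over 16 clonotype tests). DKO replicate 2 alone reached 77.9% (95% exact binomial interval 76.7 to 79.1), and the other DKO libraries lay between 3.86 and 12.5%. Drawn to 2633 reads, TRA tables held 953 ± 469 clonotypes in DKO and 2120 ± 79.3 in WT (difference of log10 means -0.438, exact p = 0.00794, adjusted p = 0.0181). For TRB, with 4 DKO and 3 WT tables, the top share was 26.6 ± 34.3% against 0.447 ± 0.317% (exact permutation p = 0.2, adjusted p = 0.229), and the difference in log10 clonotypes at equal depth was -0.546 (exact p = 0.0857, adjusted p = 0.114). Neither passed the test, although the groups did not overlap in either measure. The TRB top share was 6.43% or above in DKO and 0.78% or below in WT. Clonotypes at equal depth numbered 187.5 to 1621.3 in DKO and 2925.9 to 3135.8 in WT. Within the libraries numbered up to 3 the TRA difference was 29.1 percentage points (exact p = 0.1, the smallest that 3 against 3 can give), and within the others 8.38 (exact p = 0.333). The call was lost with any 1 WT library left out (replicate 1, 2, 3, 4 or 5), where the exact p was 0.0952 at a difference of 20.7 to 21.0 points, and without DKO replicate 2 the difference was 6.77 points (exact p = 0.00794).

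**Figure D1:**
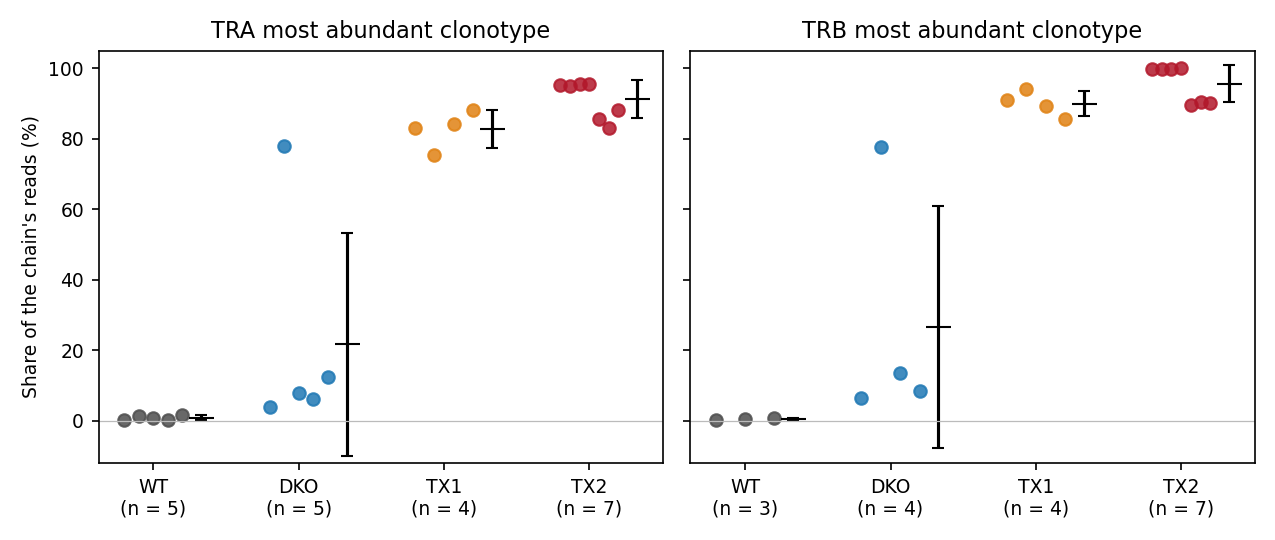
Share of TRA (left) and TRB (right) reads taken by the most abundant clonotype in each library, in percent. Points are libraries and black bars are group means with SD; the TX1 libraries sit between 75.4 and 88.1% for TRA and the TX2 libraries between 83.2 and 95.7%, while DKO replicate 2 is at 77.9% and every WT library is at 1.66% or below.

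The comparison of TX1 with DKO asks what changes once DKO cells have expanded in a recipient. Ribosome biogenesis genes rose and interferon-stimulated genes fell. Of 20 Myc and ribosome biogenesis genes, 19 rose, among them Myc itself (362 ± 127 CPM, n = 4, against 108 ± 29.2, n = 5), Polr1b, a subunit of RNA polymerase I (117 ± 33.2 against 33.4 ± 6.41), and Srm, spermidine synthase (log2 fold change 1.73 ± 0.30). Of 20 interferon-stimulated genes, 15 fell and 0 rose, with Oasl2 at -4.76 ± 0.91 and Rsad2 at -4.09 ± 0.84. Of 33 DNA damage and repair genes, 14 rose and 1 fell, with Chek1, a checkpoint kinase, at 35.6 ± 16.3 against 13.5 ± 4.60 CPM and the glycosylase Ung at 69.0 ± 25.0 against 24.8 ± 9.09. Trp53, the gene of p53, rose (log2 fold change 0.59 ± 0.15, adjusted p = 0.0265).

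Of 28 DNA replication genes 7 rose, including Mcm3 (1.09 ± 0.27) and Mcm2 (1.04 ± 0.26), and no mitosis gene of 26 passed the test. Of 16 naive genes 7 fell and 1 rose, with Cd55 at -5.73 ± 0.97 and Nsg2 at -2.34 ± 0.57. Of 22 cytotoxic genes 9 fell and 2 rose, with Gzma at -5.20 ± 1.21 and Xcl1 at -5.17 ± 0.88. Of 18 T cell receptor signalling genes 5 fell and 0 rose, including the adaptor Lat (-1.96 ± 0.25), and the adhesion gene Cd2 was at -2.02 ± 0.52. By camera the adjusted p was 5.06e-19 for ribosome biogenesis, 2.24e-11 for interferon, 5.80e-05 for DNA damage, 2.58e-05 for replication, 3.27e-05 for naive, 0.000116 for cytotoxic and 0.00323 for receptor signalling genes. With an estimated correlation the adjusted p was 0.348 for the ribosome, interferon, naive, cytotoxic and signalling genes, 0.410 for DNA damage and 0.518 for replication. Adjusted over the list alone, 20 ribosome, 18 DNA damage and 8 replication genes rose, and 16 interferon, 9 naive, 12 cytotoxic and 5 signalling genes fell. Inhibitory receptor genes (1 of 14 fell, 4 adjusted over the list alone) and cytokine receptor and JAK-STAT genes (4 of 26 rose and 4 fell, both adjusted over the list alone too) were called by camera at adjusted p = 0.0482 and 0.0407, and had 0.410 and 0.474 with an estimated correlation.

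In TX1, Zbtb16 (chromosome 9, 48654297 to 48836222) reached 170 ± 74.8 CPM (n = 4) against 8.72 ± 4.41 (n = 5), a log2 fold change of 4.28 ± 0.58. Il23r was at 78.1 ± 64.1 against 5.94 ± 3.81 CPM and the tyrosine kinase Blk at 130 ± 150 against 3.23 ± 3.81. The chemokine receptors Ccr2 (2.73 ± 0.49) and Ccr8 (2.87 ± 0.55), Il2ra, the gene of CD25 (2.23 ± 0.62), the cytokine Il4 (2.12 ± 0.49) and the stress gene Atf3 (3.64 ± 0.82) rose too. DKO cells were gated on absence of CD25 and TX1 cells were not, so the rise of Il2ra cannot be told apart from the gate. Il2ra was at 110.1, 98.35, 34.49 and 8.658 CPM in TX1 replicates 1 to 4, where DKO libraries had 9.567 to 17.36. TX1 replicate 2 held the highest Blk (336.3 CPM, other TX1 libraries 10.75 to 123.6) and Atf3 (15.49 CPM, others 1.522 to 2.575). Of the lists that hold these genes, 5 were not called. Of 18 chemokine receptor and homing genes 3 rose and 3 fell (3 and 4 adjusted over the list alone), with a median of -1.08 (camera adjusted p = 0.151). Of 15 helper lineage genes 3 rose and 1 fell (0.621), and of 13 T follicular helper genes 1 rose (0.348). Of 16 immediate early genes 2 rose (0.668), and of 5 invariant NKT markers 2 rose and 1 fell (2 and 3 adjusted over the list alone; 0.890). With an estimated correlation the adjusted p was 0.348 or above for these 5. Foxp3, the regulator of regulatory T cells, fell by 7.85 on the log2 scale (SE 1.01) to 0.0947 ± 0.0703 CPM, and Gpr83 fell by 6.57 (SE 1.03). Neutrophil markers were lower (6 of 6 measured fell), with Ngp at -8.26 ± 1.94 and S100a9 at -7.29 ± 1.56, as were the macrophage markers Lyz2 (-4.66 ± 1.09) and Csf1r (-5.36 ± 1.29). The size of these falls rested on some DKO libraries. Ngp was at 67.91 and 70.65 CPM in DKO replicates 4 and 5, labelled young, and at 1.02 to 8.039 in replicates 1 to 3. S100a9 was at 39.87 and 38.77 CPM and at 1.161 to 7.204 in these. Lyz2 was at 2.462 and 3.312 CPM in DKO replicates 1 and 2 and at 34.38 to 47.76 in the others. Csf1r was at 0.563 and 0.331 CPM and at 3.791 to 16.46 in these. Camera called as lower the markers of neutrophils (adjusted p = 0.000264), macrophages (0.00064), B cells (0.0314) and regulatory T cells (0.0352), and as higher those of gamma-delta T cells (0.00335, where 4 of 5 rose and 1 fell), and with an estimated correlation the adjusted p was 0.410 for B cells and 0.348 for the others. Trdc, the constant gene of the delta chain, was not higher. It was at 0.134 CPM in TX1 replicate 1 and 0 in the other TX1 libraries, where DKO libraries had 0.184 to 4.11. The largest rises were in Kcns3 (8.80 ± 1.53), Ankrd63 (8.43 ± 1.26), Dnah9 (7.94 ± 1.46), Flt4 (7.73 ± 1.49), Stab2 (7.65 ± 1.16) and Gcsam (7.19 ± 1.65). Their levels differed widely between TX1 libraries. Kcns3 ranged from 2.58 to 142 CPM, Ankrd63 from 5.21 to 73.3 and Dnah9 from 1.48 to 118. Flt4 ranged from 0.778 to 50.3 CPM, Stab2 from 5.49 to 222 and Gcsam from 0.502 to 67.9.

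Among the largest falls, H2-Ob was at 0.0520 ± 0.0655 against 19.5 ± 10.1 CPM. Tbxa2r, Oasl1 and Rps4l each had 3 reads in the 4 TX1 libraries together, against 19.7 ± 10.6, 9.41 ± 8.16 and 10.4 ± 5.64 CPM in DKO. Rps4l is a close copy of another ribosomal protein gene, so its level is uncertain. Cd4 (chromosome 6, 124864692 to 124888221) was at 265 ± 512 CPM in TX1 against 1430 ± 252 in DKO (log2 fold change -2.43 ± 1.83, adjusted p = 0.383): TX1 replicate 1 held 1003 CPM and the other 3 libraries 0.135 to 27.2. Tet1 (adjusted p = 0.357), Tet2 (0.594), Tet3 (0.289), Runx3 (0.832), Zbtb7b (0.684), Mki67 (0.828) and Ptprc (0.0690) did not pass the test.

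Of 13954 genes tested, 2743 differed, 1631 higher and 1112 lower in TX1, and 18.7% did not overlap between the groups, where chance gives 1.59%. Of 130 receptor segment genes 71 fell and 9 rose. The count rested on single libraries: it was 5399 without TX1 replicate 1, 1707 without TX1 replicate 2, 1326 without TX1 replicate 3, and 1596, 1748, 1356 and 1331 without DKO replicates 1, 3, 4 and 5. With the sequencing round, which was inferred from the data, as a covariate it was 2719, and in the libraries numbered up to 3 alone edgeR called 0 genes (2595 at an unadjusted p below 0.05), and leaving out the DKO libraries labelled young left 3. The young libraries are DKO replicates 4 and 5, which both subsets leave out. Of the 64 named genes that changed and had a value in every alternative, 0 kept the call in each.

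Each TX1 library was dominated by its own receptor. The top TRA clonotype took 82.7 ± 5.34% of reads (n = 4) against 21.7 ± 31.6% in DKO (n = 5; exact permutation p = 0.0238, adjusted p = 0.0458, higher than the DKO mean in 4 of 4 libraries). The TRB top share was 90 ± 3.58% (n = 4) against 26.6 ± 34.3% (n = 4; exact p = 0.0286, adjusted p = 0.0458). With productive TRA clonotypes alone the top share was 98.3 ± 3.19% in TX1 and 24.2 ± 34.7% in DKO. The second most abundant TRA sequence of each TX1 library was nonproductive, at 9.79 to 24.54% of reads. At equal depth TRA tables held 5.17 ± 3.12 clonotypes against 953 ± 469 (exact p = 0.00794, adjusted p = 0.0181). Among the libraries numbered up to 3 the TRA difference was 51.0 percentage points (exact p = 0.2), where DKO replicate 2 lies between TX1 libraries. The test of the top share lost its call (exact p = 0.0536 to 0.0571) without TX1 replicate 1, 3 or 4 or without DKO replicate 1, 3, 4 or 5, and that of the TRB share (exact p = 0.0571) without any 1 of the TX1 libraries.

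**Figure D2:**
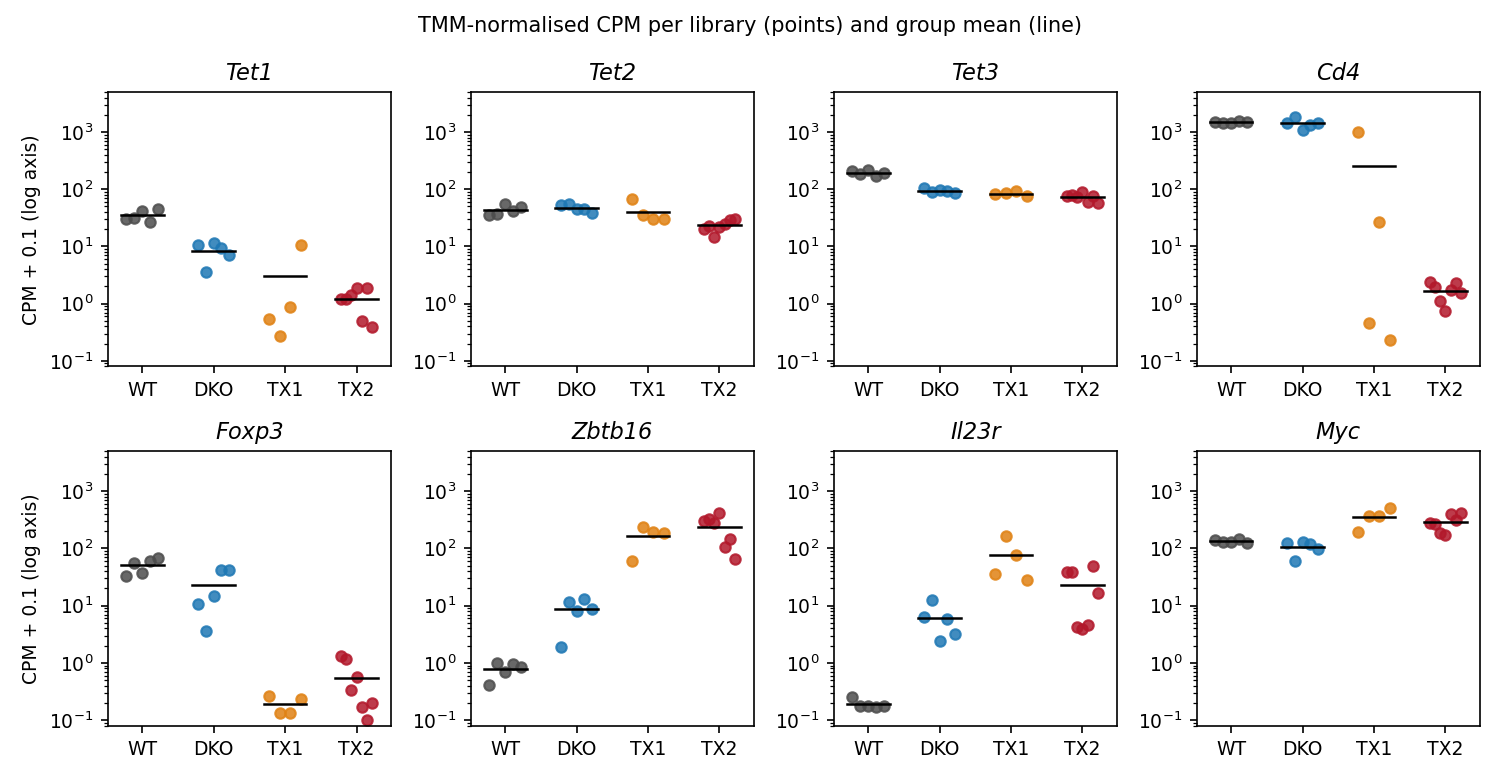
TMM-normalised CPM plus 0.1 of 8 genes per library, on a log axis. Points are libraries and black lines are group means; Cd4 stays at 1003 CPM in TX1 replicate 1 and at 27.2 CPM or below in the other libraries of transferred cells, and Zbtb16 lies between 61.5 and 415 CPM in every transferred library against at most 0.913 CPM in WT.

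The comparison of TX2 with DKO asks the same of cells transferred again. Cd4 was lost and replication genes rose. Cd4 fell to 1.57 ± 0.596 CPM (n = 7) from 1435 ± 264 (n = 5), a log2 fold change of -9.83 ± 0.33 (adjusted p = 1.59e-08), in libraries sorted without a CD4 gate. Of 28 DNA replication genes, 27 rose, with Mcm2 at 553 ± 75.0 against 194 ± 43.3 CPM and Mcm10 at 65.6 ± 22.2 against 24.9 ± 12.3. Of 20 ribosome biogenesis genes, 19 rose, with Srm (log2 fold change 1.90 ± 0.24), Polr1b (1.52 ± 0.22) and Myc (284 ± 88.7 against 108 ± 28.9 CPM). Of 20 interferon-stimulated genes, 18 fell and 0 rose, with Oas2 at -5.18 ± 1.03, Rsad2 at -4.03 ± 0.95 and Mx1 at -3.96 ± 0.53.

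Of 33 DNA damage genes 20 rose and 3 fell, with Chek1 at 48.6 ± 3.76 against 13.5 ± 4.47 CPM and Ung at 1.54 ± 0.20 on the log2 scale, and Trp53 rose by 0.79 ± 0.08. Of 19 p53 targets 7 fell and 2 rose, Pmaip1 at -2.24 ± 0.31 and Fas at -1.62 ± 0.46 among those that fell; the list's median was 0.07 and its mean -0.16. Of 15 glycolysis genes 11 rose, with Hk2 at 39.1 ± 6.83 against 10 ± 3.51 CPM. Of 26 cytokine receptor and JAK-STAT genes 14 fell and 2 rose: Stat4 fell from 94.5 ± 9.80 to 0.282 ± 0.188 CPM and Socs3 from 168 ± 65.9 to 5.44 ± 4.03. Of 18 activation genes 6 fell and 1 rose, and of 18 receptor signalling genes 7 fell and 1 rose. Cxcr3 was at -6.37 ± 0.40, Tnfrsf4, the gene of OX40, at -6.34 ± 0.47, Anxa2 at -4.89 ± 0.53 and Lat at -1.83 ± 0.21. By camera the adjusted p was 1.69e-09 for replication, 1.38e-09 for ribosome biogenesis, 6.25e-07 for interferon, 8.96e-05 for DNA damage, 0.00116 for glycolysis, 0.000236 for JAK-STAT, 0.0138 for activation and 0.00173 for receptor signalling genes, and 0.402 for p53 targets. With an estimated correlation the JAK-STAT genes kept the call (adjusted p = 0.0277), and the other called lists had an adjusted p of 0.506 or above. All list tests of TX2 count recipients of a clone as separate, and they were not run with clones summed. Adjusted over the list alone, 27 replication, 19 ribosome, 20 DNA damage and 11 glycolysis genes rose, and 18 interferon, 14 JAK-STAT, 6 activation and 7 signalling genes fell. Of 26 mitosis genes 9 rose (1 adjusted over the list alone; camera adjusted p = 0.00245, and 0.749 with an estimated correlation), and of 16 naive genes 10 fell and 2 rose (10 and 3 adjusted over the list alone; 0.0272 and 0.612).

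Zbtb16 (235 ± 133 against 8.74 ± 4.44 CPM), Ccr8 (139 ± 109 against 4.37 ± 1.72 CPM) and Il4 (log2 fold change 2.79 ± 0.62) rose in TX2. Dapl1 was called higher as well (2.60 ± 0.86). These rises differed between the 2 clones of TX2: Dapl1 was at 75.3 to 94 CPM in replicates 1 to 4 and at 2.77 to 15.9 in 5 to 7, where DKO libraries had 1.14 to 13.6, and Il4 at 13 to 16.1 and at 1.58 to 6.7, where DKO libraries had 0.457 to 2.50. The naive genes Satb1 (-2.16 ± 0.30) and S1pr1 (-2.08 ± 0.53) fell. Foxp3 (-5.65 ± 0.96), Gpr83 (-7.67 ± 0.82), Ctla4 (-4.98 ± 0.58), Gzma (-5.70 ± 1.30), Slamf1 (-3.68 ± 0.55), Ctss (-4.46 ± 0.97) and the immediate early gene Junb (-2.55 ± 0.43) fell. Several lists that hold these genes were not called by camera. Of 13 helper lineage genes 6 fell and 3 rose (median -1.03, adjusted p = 0.0692), and of 8 regulatory T cell markers 5 fell (0.0906). Of 21 cytotoxic genes 10 fell and 2 rose (0.137), and of 19 chemokine receptor genes 8 fell and 3 rose (0.137). Of 14 inhibitory receptor genes 4 fell, 3 adjusted over the list alone, and 1 rose (0.360). Of 16 immediate early genes 4 fell and 2 rose (0.498), and of 14 macrophage markers 1 fell and 1 rose (0.498). Of 12 follicular helper genes 3 fell and 1 rose (0.562), and of 5 invariant NKT markers 3 fell and 2 rose (0.846). Erythroid (5 of 6 rose, 0.527) and DNA methylation genes (7 of 14 rose and 5 fell, 0.562), some of which follow, were not called either. Apart from the inhibitory receptors the counts were the same adjusted over the list alone. With an estimated correlation the adjusted p of these 11 lists was 0.506 or above. Tet1 (-2.92 ± 0.46), Tet2 (-1.04 ± 0.16, 23.2 ± 5.01 against 47.9 ± 6.22 CPM) and Tet3 (-0.40 ± 0.12) were each lower than in DKO, and Uhrf1 rose (1.78 ± 0.22). Zbtb7b (-1.03 ± 0.27) and Ptprc (-0.39 ± 0.11) fell, and Runx3 (adjusted p = 0.126) and Mki67 (adjusted p = 0.383) did not pass the test. Ly6c2, which has a near-identical neighbour, rose (4.76 ± 1.05), with 79.1 to 109.6 CPM in TX2 replicates 1 to 4 and 493 to 1823 in 5 to 7. Hbb-bs, one of a family of close globin copies, rose (5.82 ± 1.82), with 275 CPM in TX2 replicate 7 and at most 14.3 in the other 6.

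Lgi1 had no read in DKO; its rise in TX2 (17.3 ± 24.1 CPM) was carried by replicates 5 to 7, at 18 to 55.8 CPM, with 0.0673 to 0.478 in 1 to 4. Pcdh7 was likewise at 7.44 to 40.8 CPM in replicates 5 to 7 and at 0.333 to 0.581 in 1 to 4. Sema5a (9.30 ± 1.58) and Wnt6 (9.98 ± 1.21) were the other large rises with more than 3 reads in DKO. They differed between the clones too. Sema5a was at 5.61 to 10.25 CPM in TX2 replicates 1 to 4 and at 56.8 to 227.7 in 5 to 7. Wnt6 was at 46.4 to 99.3 CPM in replicates 1 to 4 and at 3.51 to 13.5 in 5 to 7. Gabra4 and Pcdh7 had 1 read each in the 5 DKO libraries together and Apba2 had 3, against 47.2 ± 44.0, 11.2 ± 16.5 and 21.5 ± 10.7 CPM in TX2. Il21 had 1 read in the 7 TX2 libraries together, Cd109 had 2 and Itgb8 had 3, against 79.3 ± 124, 32.1 ± 33.7 and 17 ± 17.1 CPM in DKO. Dsp (-10.11 ± 1.05) and Car5b (-9.37 ± 0.81) also fell.

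Of 14034 genes tested, 7255 differed, 3587 higher and 3668 lower in TX2, and 33.2% did not overlap, where chance gives 0.253% if recipients of a clone are taken as separate. Of 116 receptor segment genes 59 fell and 11 rose. The 7 TX2 libraries were dominated by 2 clones, and with recipients of each clone summed 4555 genes differed. Of 93 named genes called, 19 lost the call with clones summed. With the sequencing round as a covariate 4322 differed, in the later round alone 4334, and with an absolute log2 fold change above 1 it was 3365.

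The top TRA clonotype took 91.2 ± 5.43% of reads in TX2 (n = 7), 69.5 percentage points above DKO (exact permutation p = 0.00126, the smallest the design allows, adjusted p = 0.0101), and was higher in 7 of 7 TX2 libraries than in any DKO library. In the later round alone the difference was 81.9 points (exact p = 0.0278, the smallest that 7 against 2 can give). The 2 DKO libraries of that round are the ones labelled young. These tests treat the recipients of a clone as separate; with each of the 2 clones averaged the difference was 68.8 points (exact p = 0.0476, the smallest that 2 against 5 can give). The TRB top share was 95.7 ± 5.22% (n = 7; exact p = 0.00303, adjusted p = 0.0121). With productive TRA clonotypes alone the top share in TX2 was 99.86 ± 0.113%. TX2 replicates 1 to 4 carried the same TRA and TRB receptor, and TX2 replicates 5 to 7 carried another, which was also the receptor of TX1 replicate 3.

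The comparison of TX2 with TX1 asks what a second transfer adds. Dstn, which encodes an actin-depolymerising protein (chromosome 2, 143915320 to 143943324), rose from 51.1 ± 5.23 CPM (n = 4) to 106 ± 17.9 (n = 7), a log2 fold change of 1.05 ± 0.14 (adjusted p = 0.0291). Zfp287, a zinc finger gene (chromosome 11, 62700356 to 62731905), fell from 19.2 ± 6.62 to 4.50 ± 0.780 CPM (-2.09 ± 0.23, adjusted p = 0.0257). The other calls lie outside the rule for named genes and were named after their values were seen: Fcrl5 at 2.51 ± 1.24 against 0.0165 ± 0.0331 CPM and Scin at 0.984 ± 0.485 against 0.00842 ± 0.0168 were higher, and Grik2 (-2.81 ± 0.38) and Tnnt3 (-3.37 ± 0.45) were lower (adjusted p = 0.0291 each). Cd4 was at 1.58 ± 0.602 against 271 ± 523 CPM (adjusted p = 0.0874), and Tet1 (adjusted p = 0.398), Tet2 (0.132), Tet3 (0.362), Zbtb7b (0.164), Runx3 (0.523), Trp53 (0.323), Myc (0.546), Mki67 (0.410) and Ptprc (0.407) did not pass the test.

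No member of any gene list passed the test over all genes. By camera, mitosis (adjusted p = 5.37e-13), glycolysis (1.94e-05) and DNA replication (0.000152) genes stood higher in TX2 as lists, with median log2 fold changes of 0.89, 0.37 and 0.32, and so did macrophage (0.00498), erythroid (0.0200) and B cell (0.0448) markers. With an estimated correlation the adjusted p was 0.870 for all 6. These list tests, too, count recipients of a clone as separate. Adjusted over the list alone, 0 mitosis, 6 glycolysis, 0 replication, 2 macrophage, 7 erythroid and 1 B cell genes rose. In 4 mitosis genes, picked after their values were seen, the TX2 mean lay below TX1 replicate 4, the only TX1 library of the TX2 round. It had Aurkb at 110.1, Birc5 at 111.3, Ccnb2 at 97.88 and Mki67 at 610.6 CPM. The TX2 libraries had 63.22 to 132.3, 69.71 to 106.9, 67.92 to 97.53 and 296.4 to 549.2, and the other 3 TX1 libraries had at most 37.0, 42.73, 39.71 and 284.9. Cd79a, a B cell gene, was at 17.1 to 36.7 CPM in TX2 replicates 5 to 7 and at 0.889 or below in the other TX2 and the TX1 libraries. The macrophage genes Lyz2 and Csf1r were at 37.5 to 56.7 and 6.20 to 10.6 CPM in TX2 replicates 5 to 7. In the other TX2 libraries they were at 1.675 to 11.75 and 0.471 to 1.09 CPM. Hba-a1, an erythroid gene, was at 253 CPM in TX2 replicate 7 and at most 17.2 in the other TX2 libraries.

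Of 13907 genes tested, 6 differed, 3 higher and 3 lower, and 4.0% did not overlap between the groups, where chance gives 0.606% if recipients of a clone are taken as separate; 2992 genes had an unadjusted p below 0.05 and DESeq2 called 1435. The 7 TX2 libraries hold 2 clones, 1 of them also that of TX1 replicate 3. With recipients of one clone summed edgeR called 0 genes (589 at an unadjusted p below 0.05), with Dstn at 1.07 ± 0.16 and Zfp287 at -2.08 ± 0.42 (adjusted p = 0.862 each): the folds held while the samples fell to 2 against 4, so the calls rest on counting recipients of a clone as separate. Of the TX1 libraries 1, replicate 4, shares the inferred round of the TX2 libraries, so that round and transfer were largely confounded; with the round as a covariate, a fit that rests on that library, edgeR called 0 (504 at an unadjusted p below 0.05). The count was 0 without TX1 replicate 2 (unadjusted 2043) or without any of TX2 replicates 1 to 5 (unadjusted 2499 to 2703), 3 without TX2 replicate 7, 23 without TX1 replicate 3, 119 without TX2 replicate 6 and 1318 without TX1 replicate 4. The TRA top share was 8.52 percentage points higher in TX2 (exact permutation p = 0.0455, adjusted p = 0.0662), which did not pass after adjustment, and 1.54 points with productive clonotypes alone (exact p = 0.270).

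The title of the series names genomic instability, so expression was compared along the chromosomes. The SD of median expression over 19 autosomes was 0.141 ± 0.052 (log2, SD, n = 4) in TX1 and 0.152 ± 0.011 (n = 7) in TX2, against 0.045 ± 0.012 (n = 5) in DKO and 0.046 ± 0.039 (n = 5) in WT. Chromosome 17 stood out: its median lay between 0.35 and 0.52 above WT in 10 of 11 transferred libraries, which by their receptors hold 4 of 5 clones, at 0.13 in TX1 replicate 1, and between -0.16 and 0.05 in the WT and DKO libraries. Chromosome 6 was raised in TX2 replicates 1 to 4 (0.23 to 0.42), chromosome 15 in TX1 replicate 3 and TX2 replicates 5 to 7 (0.29 to 0.46) and chromosome 2 in TX1 replicate 2 (0.42). Some shifts parted libraries of 1 clone: chromosome 16 was at 0.28 in TX1 replicate 3 and 0.30 in TX2 replicate 6 and at 0.08 and 0.09 in TX2 replicates 5 and 7, and chromosome 2 was at 0.20 in TX2 replicates 1 and 2 and at 0.04 and 0.03 in 3 and 4. Chromosome 6 was at -0.23 to -0.14 in TX1 and in TX2 replicates 5 to 7. Of tested genes on chromosome 17, 29.9% rose in TX1 against DKO and 41.3% in TX2 against DKO, where 10.9% and 24.7% of genes on other autosomes rose.

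Imbalance was higher in TX1 than in DKO by 0.096 (two-sided exact permutation p = 0.00794, adjusted p = 0.0119 over 3 tests, higher in 4 of 4 libraries than the DKO mean) and in TX2 than in DKO by 0.107 (exact p = 0.00126, adjusted p = 0.00378, higher in 7 of 7). The 7 TX2 libraries hold 2 clones; with each clone averaged the difference was 0.108 (exact p = 0.0476, the smallest that 2 against 5 can give). DKO and WT differed by -0.001 (exact p = 0.992), but without WT replicate 5, whose own imbalance was 0.113, DKO stood higher by 0.021 (exact p = 0.0159). Among the libraries numbered up to 3 the TX1 difference was 0.092 (exact p = 0.1, the smallest that 3 against 3 can give), and for TX2 the difference was 0.113 in the later round alone (exact p = 0.0278). Between DKO and WT it was 0.016 among the libraries numbered up to 3 (exact p = 0.2) and -0.025 in the later round (exact p = 1.0).

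**Figure D3:**
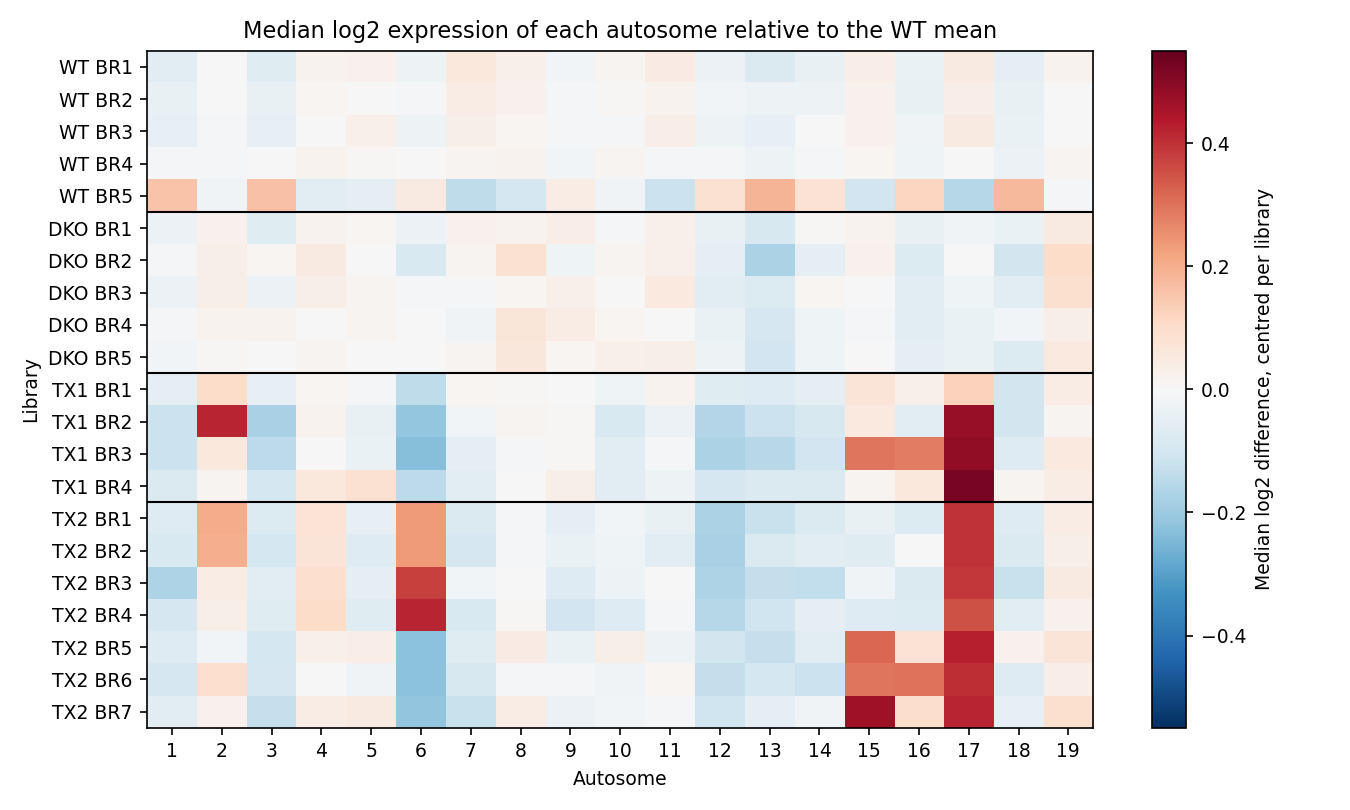
Median log2 expression of each autosome (columns) in each library (lines of the map) relative to the WT mean, centred per library; red is higher and blue lower. Chromosome 17 is raised by 0.35 to 0.52 in 10 of 11 libraries of transferred cells, and chromosome 15 by 0.29 to 0.46 in TX1 replicate 3 and TX2 replicates 5 to 7.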

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

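The libraries below were set apart by a test fixed before the data were examined, in which the highest or lowest library of a group of 4 to 10 lies far from its nearest neighbour relative to the whole range. It was run on 306 groups of values, on measures per library and on printed genes only, a restriction made after a wider run had been seen. It set apart 51 values, where chance gives about 1 in 20 groups, and 21 of them were in DKO replicate 2, 7 in TX1 replicate 1 and 5 in WT replicate 5.

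DKO replicate 2 held the highest share of its top clonotype, 77.9% for TRA (next library 12.5%) and 77.8% for TRB (next 13.6%). It was also the highest DKO library for Cadm1 (61.2 CPM), Epha3 (185 CPM against 11.1 in the next), Mmp10 (83.1), Icos (1099), Il21 (301), Pdcd1 (400.0), Lag3 (1038), Cd160 (181), Pmaip1 (65.4), Ccr4 (284), Pax5 (111), Zbtb7b (273), Atf3 (0.920), Itgb8 (46.5), Car5b (67.5) and Tnfrsf4 (218). It was the lowest for Tbc1d30 (0.0736 CPM) and Cd2 (107), and had the highest autosome imbalance of the group (0.066, next 0.043). No biological explanation was tested for these values. It is the only DKO library labelled female, so its sex cannot be told apart from its other traits.

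TX1 replicate 1 kept Cd4 at 1003 CPM (next library 27.2) and had the highest TX1 level of Tet2 (66.9 CPM), Rsad2 (3.15), Ngp (0.368), Tbxa2r (0.1) and Rps4l (0.1), and the lowest chromosome 17 median (0.13, next 0.48). TX1 replicate 4 had the highest depth (30.7 M reads assigned to genes, next 28.6) and Tet1 (10.6 CPM, next 0.779), and TX1 replicate 2 the highest Atf3 (15.5 CPM).

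WT replicate 5 stood apart in autosome imbalance (0.113, next 0.043), chromosome 17 median (-0.16), Cd55 (101 CPM), Tpi1 (38.3) and Zbtb7b (223). Among other WT libraries, replicate 4 was highest for Mmp10 (0.284 CPM) and Ccr4 (28.4), replicate 2 for Pdcd1 (39.6) and replicate 1 for Il23r (0.152).

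Among TX2 libraries, replicate 6 was highest for Anxa2 (33 CPM), Ctla4 (14.1) and Slamf1 (6.76), replicate 7 for Hbb-bs (275, next 14.3), Rsad2 (6.80) and Il21 (0.0322, 1 read), replicate 5 for Gzma (11.5), and replicate 1 for TRB clonotypes at equal depth (7.3). In DKO, replicate 4 held the single reads of Pcdh7 and Gabra4 (0.0321 CPM each), and replicate 5 was highest for Hbb-bs (1.96).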

How the results depend on the processing

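The alternatives built on sequencing rounds and on the TX2 clones were chosen after the data were seen. For 27 main results there were 383 alternative values: 298 were judged the same, 68 weaker, 16 stronger and 1 reversed, and 17 results changed at least once. Counts of genes and of called lists were judged the same within a ratio of 1.5 of the main count. Permutation tests were judged by direction and side of the threshold. Single tests were judged here at an unadjusted p of 0.05. Where no cause is given, the cause was not tested.

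For DKO against WT the count was 2541 with an absolute log2 fold change above 1, and, with fewer samples, 3829 in libraries numbered up to 3 and 3217 in the others. It was 5044 to 6464 with 1 library left out. For TX1 against DKO the count was 4118 by DESeq2, 1369 above the fold threshold, 1413 in males, 70 with replicate numbers as blocks, 3 without DKO labelled young and 0 in libraries numbered up to 3 (edgeR, 2595 at an unadjusted p below 0.05; DESeq2 was not run on that subset), and 1326 to 5399 with 1 library left out. For TX2 against DKO it was 3365 above the fold threshold, 4322 with the round as covariate, 4334 in the later round and 4555 with recipients of a clone summed, and 6432 to 7125 with 1 library left out. Blocks gave 5752 for DKO against WT and 5967 for TX2 against DKO. The numbers were not taken as pairing the samples: deviations of same-numbered libraries correlated at -0.055 to 0.406 (DKO against WT), -0.162 to 0.270 (TX1 against DKO), -0.110 to 0.163 (TX2 against DKO) and -0.243 to 0.313 (TX2 against TX1), and in no comparison did every library correlate best with its own number. In DKO against WT, same-numbered libraries were more alike on average, which the sequencing rounds could explain.

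For TX2 against TX1 the count was 1435 by DESeq2, 13 without a filter, 1694 in 1 fit of all groups, 664 with sex as covariate, 839 in males, 1 with the strand column, 563 with blocks, 16 without receptor segments, 1496 with TX2 replicates 1 to 4 and 183 with 5 to 7. The female libraries here were TX1 replicate 3 and TX2 replicates 5 to 7, which share 1 receptor. Sex therefore cannot be told apart from clone in these alternatives. By edgeR it was 0 with the round as covariate, which rests on TX1 replicate 4 (504 at an unadjusted p below 0.05) and 0 with clones summed (589), and 0 to 1318 with 1 library left out.

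Camera with an estimated correlation called 0, 0, 1 and 0 lists for DKO against WT, TX1 against DKO, TX2 against DKO and TX2 against TX1, and fry called 15, 13, 17 and 0. The main test called 9, 14, 10 and 6; in TX1 against DKO, fry did not call DNA replication (adjusted p = 0.109) and JAK-STAT genes (0.061), which camera called.

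The TRA top share difference of DKO and WT was 29.1 points in libraries numbered up to 3 (exact p = 0.1) and 8.38 in the later round (0.333), and 6.77 to 25.3 with 1 library left out. That of TX1 and DKO was 51.0 in libraries numbered up to 3 (0.2) and 56.6 to 75.1 with 1 left out. That of TX2 and TX1 was 1.54 among productive clonotypes (0.270), 8.53 with at least 2 reads (0.0515) and 6.07 to 10.3 with 1 left out. For TRB, TX1 against DKO, it was 58.8 (0.1), and 56.7 to 80.5 with 1 left out. In libraries numbered up to 3, where 3 against 3 cannot pass, clonotype numbers differed by -0.524 (TRA, DKO against WT; -0.309 in the later round), -2.26 (TRA, TX1 against DKO) and -2.34 (TRB). Autosome imbalance of DKO and WT reversed to 0.021 without WT replicate 5 (range with 1 left out -0.01 to 0.021), and that of TX1 and DKO was 0.026 among genes not called, a filter that by its making removes genes a shift of a whole chromosome would change and so tests nothing, and 0.092 in libraries numbered up to 3.

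Of named genes called that had a value in every alternative, 61 of 87 (DKO against WT), 0 of 64 (TX1 against DKO), 53 of 82 (TX2 against DKO) and 0 of 2 (TX2 against TX1) kept the call in each. Log2 fold changes that reversed were Gins2 (-0.45, strand column), Slc2a3 (-0.16, TX2 replicates 5 to 7), Fcer2a (-0.62 in males, -0.30 in TX2 replicates 1 to 4), and Car1 (-0.56 and -0.34 in these). In TX2 against TX1 the values of Cd4 (3.55 in the later round, 3.54 with round as covariate) and Mki67 (-0.45 and -0.47) also changed sign, but rest on TX1 replicate 4, the only TX1 library of that round, and describe no reversed group difference. For Tet1, TX2 vs TX1, it was 0.60 with blocks and -1.76 to 1.24 with 1 library left out, the highest without TX1 replicate 4.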

Other observations

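All tests of explanations and of other splits in this part, and their bounds, were chosen after the results were seen. Among 40 splits of the libraries per comparison, the real one gave the most genes in each case (1 of 40): 5951 against at most 1 for DKO and WT, 2743 against at most 788 for TX1 and DKO, 7255 against at most 1425 for TX2 and DKO, and 6 against at most 0 for TX2 and TX1, where edgeR called 0 and other tools were not run on the splits. For TX2 and DKO these splits shuffled recipients of 1 clone as separate; with the 2 clones summed, the real split gave the most genes of all 21 (1 of 21), 4555 against at most 11. For TX1 and DKO 40 of 126 possible splits were drawn. There edgeR called 0 genes in libraries numbered up to 3 (2595 at an unadjusted p below 0.05) and 3 without DKO labelled young. For the first 3 comparisons the drawn splits argue against chance assignment of libraries, without excluding it. For TX2 and TX1 it stays open, since libraries of 1 clone were shuffled as separate and by edgeR the count was 0 with clones summed (589 at an unadjusted p below 0.05). There the inferred round differs almost as the groups do, and the count was 0 with the round as covariate (504), a fit that rests on 1 TX1 library.

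Chromosome 17 was raised in 10 of 11 libraries of transferred cells, which hold 4 of 5 clones. A single stretch or a few genes were argued against, since the median of each of 3 equal parts of the chromosome was 0.26 or higher in those 10 libraries and 61.4 to 71.7% of its genes lay above 0. The profile that set WT replicate 5 apart has a low chromosome 17 (-0.16), and chromosomes 1, 3 and 13, which were high in it (0.16, 0.16 and 0.19), lay below 0 in the 10 libraries, as a reversed profile would have them, while chromosome 7, low in it (-0.14), was at most -0.01 there, as a reversed profile would not have it. That profile as the whole cause was argued against: once it was scaled to the other autosomes and removed, the chromosome 17 median was still 0.33 or higher in each of the 10. An extra copy may underlie the pattern: 3 copies in place of 2 give 0.58 on the log2 scale, and the highest median was 0.52. Copy number was not measured here, and regulation of many genes of this chromosome stays open.

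TX1 replicate 2, labelled male, had Xist at 0.106 CPM, where female libraries had at least 233. Its highest level of 4 Y-linked genes was 0.212 CPM, where other male libraries had at least 22.1. Loss of the Y chromosome from the dominant clone may explain this. It cannot be told apart from a female mouse under a male label whose clone lost the inactive X, since neither Y-linked genes nor Xist reached 1 CPM.

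TX1 replicate 3 and TX2 replicates 5 to 7 carried the same receptor. Carried-over reads were argued against, since its TRA sequence took at least 83.19% of reads in these 4 libraries and dominant sequences took at most 0.29% elsewhere. A library deposited under 2 labels was argued against by a chi-square per gene of 73.7 or higher between them. All 4 abundant sequences of TX1 replicate 3 were found in the 3 TX2 libraries, which is consistent with descent from 1 clone. Chromosome 15 was raised in the same 4 libraries (0.29 to 0.46) and was at most 0.07 in the other transferred libraries. Chromosome 16 was raised in 2 of the 4 (0.28 in TX1 replicate 3, 0.30 in TX2 replicate 6).

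Reads of the canonical invariant NKT alpha chain numbered 0 in each of the 11 libraries of transferred cells, where 0 allows up to 0.045 to 0.114% of TRA reads. Single WT and DKO libraries, sorted on absence of the CD1d tetramer, had 0 to 3 such reads. The absence is therefore not particular to transferred cells, whose libraries were each dominated by 1 receptor. WT replicates 2 and 5 had the same top TRA clonotype, at 1.48% (95% exact binomial interval 1.17 to 1.85) and 1.66% (1.38 to 1.97).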
